A study of Rattus norvegicus with 6 samples.

How the data were processed

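RNA was measured in 6 cultures of UMR106-01, a rat osteosarcoma cell line with properties of osteoblasts, on 1 Affymetrix rat expression array per culture. Per the labels' protocols, cells were seeded at 100000 per cm2 in medium with 10% fetal bovine serum and collected at 76 h. At 64 h they were given fresh medium with 6.5 mM beta-glycerol phosphate, which for the treated cultures also held AEBSF, a serine protease inhibitor, at 400 µM. Groups and replicate numbers were taken from the sample titles: 3 mineralizing cultures and 3 mineralizing cultures with AEBSF, which the design text describes as triplicate cultures on each side. Total RNA was labelled with biotin by the 1-cycle protocol, per the labels.

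The deposited table holds 1 intensity per probe set and array, a MAS5 signal made in GCOS per the submitters' processing notes, for 31099 probe sets. MAS5 combines the perfect-match and mismatch probes of a probe set into 1 value per array. Versions of both tools, the scaling target and detection calls are not given in the sources used here. The scale was read from the values: they were positive, not whole and not log transformed, and the mean after leaving out the lowest and highest 2% was 500.15 or 500.16 on every array, as scaling of each array to a common target gives. Such scaling sets the arrays' overall level equal, so a change in total RNA per cell cannot be read from these values. All 6 columns were used. No pair of arrays was a copy: of 31099 probe sets, at most 2 had equal values in any of the 15 pairs of arrays.

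Probe sets were named from a platform annotation table. Of 31042 probe sets other than the 57 controls, 20826 had exactly 1 gene symbol, 436 had several and 9780 were unnamed here. Symbols of 20758 of the 20826 were updated through their Entrez identifier to the symbols of the RefSeq annotation of assembly GRCr8; that table was used for names alone and no coordinates are given, since the array's design names no genome build. Genes were not named from probe sets with several symbols.

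Values were tested as log2 of the signal with no added constant and no further normalization, in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with a variance prior that follows the mean signal), for the contrast AEBSF minus mineralizing. Tested were the 18625 probe sets whose mean log2 signal over all 6 arrays lay above the 40th percentile, which corresponds to a signal of 67.2. Adjusted p-values are from the Benjamini-Hochberg method over these 18625 probe sets, with a threshold of 0.05. A gene was represented by its probe set with the highest mean signal over all 6 arrays, chosen without regard to group, which gave 9864 tested genes. Group values are means ± SD of the signal over 3 arrays, and SE is the standard error of the log2 fold change from limma. Arrays limit the precision by their number, 3 per group.

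Before the data were examined, 33 gene lists were written from textbook knowledge: pathways of sterols, protein folding, secretion, matrix, mineralization, stress, cell cycle and signalling, and markers of osteocytes, chondrocytes, adipocytes, macrophages and osteoclasts, muscle and endothelium. Some members, Col11a1, Fn1, Phex and Dmp1 among them, are genes that published work on this culture model and inhibitor singled out, possibly on these cultures, so their direction is not independent evidence. The lists hold 542 different genes; 382 were tested, 99 lay below the signal filter, and 61 had no probe set with exactly 1 symbol of that name and were not analysed here. Each list was described by the number of tested members past the threshold, adjusted over all probe sets and over the list alone. The 28 lists with at least 5 tested members were compared with all other tested genes by limma camera with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 28 lists. Camera with an estimated correlation and limma fry were run as alternatives. Fry tests whether the genes of a list move one way on balance and makes no comparison with other genes.

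The genes named in the text follow a rule fixed before the data were examined. It takes the 15 largest rises and 15 largest falls among genes past the threshold whose 3 values in one group all lay beyond the 3 of the other. It adds up to 6 called members of each list by size of change (or, where fewer than 2 members passed, up to 3 with the highest signal), and 24 genes fixed by name. This gave 158 named genes, of which 122 passed the threshold. Of the genes fixed by name, Dmp1 and Bglap lay below the signal filter, and 5, Hmgcs1, Runx2 and Sp7 among them, had no probe set with exactly 1 symbol and were not analysed here. Of 34 named genes past the threshold with several tested probe sets, 23 had another that passed in the same direction, 11 had none other that passed, and 0 had one that passed in the opposite direction.

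Alternatives were quantile normalization, centring each array on its median, adding 16 or 64 to each signal, no signal filter or a filter at the 60th percentile, a constant variance prior, a robust variance prior, the replicate number as a block, the mean of a gene's probe sets, and leaving out each array in turn. Scaling each array to its hybridization controls (bacterial and phage transcripts added to every sample) was added after seeing the data. Array measures were compared by exact two-sided permutation tests, which cannot give a p under 0.1 for 3 against 3. The fit was tested on simulated data in which 200 of 18625 probe sets were changed, against 2495 that passed in the real data. Of 50 probe sets changed at each size, it recovered 10% at 1.25-fold, 52% at 1.5-fold, 76% at 2-fold and 86% at 3-fold. Of its 123 calls, 11 (8.9%) were false. With fewer changed probe sets the Benjamini-Hochberg adjustment is stricter, so the rates recovered do not carry over to the real data. Camera, tested on 20 simulated lists of genes that varied independently, called the 1 shifted list and 0 of the others. That cannot test the preset correlation for lists whose members vary together. Estimated correlations of the real lists ran from -0.12 for osteocyte markers to 0.842 for ribosomal proteins.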

Results

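Gene expression was measured in 6 cultures of UMR106-01 cells, a rat osteosarcoma line used as a model of osteoblasts, the cells that lay down bone matrix. All cultures were re-fed 64 h after plating with medium holding 6.5 mM beta-glycerol phosphate, a phosphate source for mineral, and 3 of them also received 400 µM AEBSF, an irreversible inhibitor of serine proteases that the series title names as a mineralization inhibitor. RNA was taken 12 h later from the 3 mineralizing cultures and the 3 AEBSF cultures. Each culture gave 1 array of MAS5 signals, of which 18625 probe sets, standing for 9864 genes, were bright enough to be tested. The comparison asks which transcripts differ when the inhibitor is present.

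With AEBSF, genes of the extracellular matrix and of protein folding in the endoplasmic reticulum (ER) fell, and genes of the proteasome rose. Limma camera placed these 3 lists apart from the other genes with a preset correlation between genes, but not with an estimated one (adjusted p = 0.221, 0.274 and 0.321 with an estimated correlation). Col1a2, a chain of type I collagen, fell 2.18-fold, from a signal of 3334 ± 139 to 1534 ± 171 (SD, n = 3 cultures each; log2 fold change -1.13, SE 0.08, limma adjusted p = 1.27e-05). Pdia4, a disulfide isomerase of the ER, fell 1.97-fold (log2 fold change -0.98, SE 0.09). Psmd1, a proteasome subunit, rose 1.45-fold (log2 fold change 0.54, SE 0.07), and outside these lists Gsta1, a glutathione transferase, rose 2.38-fold, from 256 ± 9.61 to 615 ± 99.4 (limma adjusted p = 0.00016).

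In limma, 1608 of 9864 genes (16.3%) passed an adjusted p of 0.05, 699 higher and 909 lower with AEBSF, and most changes were small, with a median of 1.28-fold among the genes that passed. Of these, 27 genes changed at least 2-fold, 4 higher and 23 lower. Among probe sets, 2495 of 18625 (13.4%) passed, 1115 higher and 1380 lower, and 50 of them changed at least 2-fold, 11 higher and 39 lower. The number of probe sets past the threshold was 1203, 1239 and 1502 without mineralizing culture 1, 2 or 3, 1626 without AEBSF culture 1, and 885 with a constant variance prior. Scaling the arrays to their hybridization controls, a choice made after seeing the data, moved the median log2 fold change of all genes from 0.002 to -0.144 and the split of probe sets to 119 higher and 2457 lower. The rises given here are therefore rises relative to the other genes on the array.

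**Figure D1:**
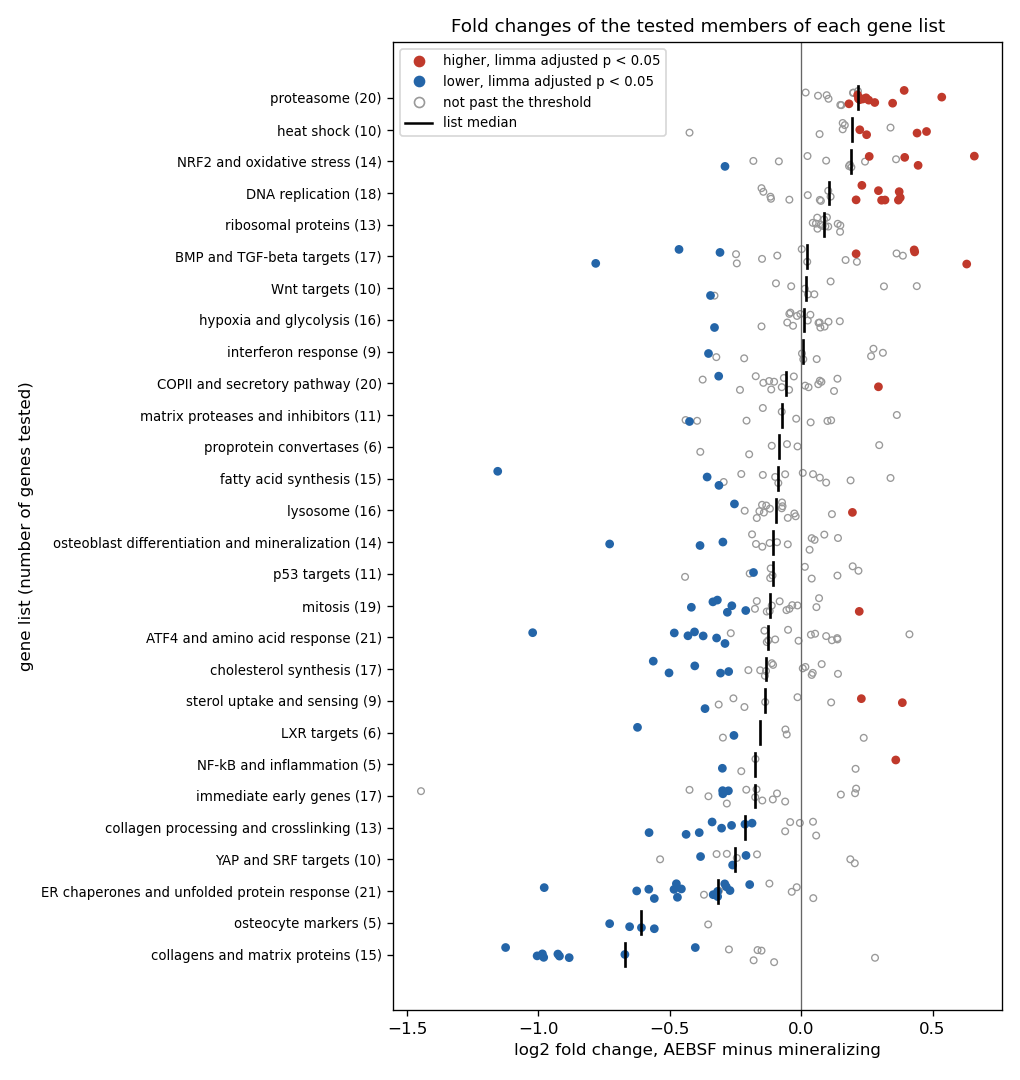
Log2 fold changes (AEBSF minus mineralizing, x axis) of the tested members of each gene list with at least 5 of them (rows, with the number tested). Filled points passed limma's adjusted p threshold of 0.05 (red higher, blue lower), open points did not, and black bars are list medians, which ran from -0.67 for collagens and matrix proteins to 0.22 for the proteasome.

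Collagens and other structural proteins of the matrix had the lowest median of the 28 lists compared. Of 15 tested members 9 fell, 0 rose and 6 did not pass, with a list median log2 fold change of -0.67. The cartilage-type fibrillar collagen chain Col11a1 fell from 3636 ± 143 to 1813 ± 111 (2.01-fold; log2 fold change -1.01, SE 0.06, limma adjusted p = 6.55e-06). Fn1, which encodes the matrix glycoprotein fibronectin, fell from 5282 ± 259 to 2668 ± 69.7 (1.98-fold; -0.98, SE 0.06, limma adjusted p = 5.09e-06). The tenascins Tnn and Tnc and the collagen chain Col12a1 fell 1.97-, 1.90- and 1.89-fold, and Col1a1, the other chain of type I collagen, fell 1.59-fold. The count was also 9 adjusted over the list alone, and limma camera placed the list below the other genes (adjusted p = 6.32e-08; adjusted p = 0.221 with an estimated correlation). Col11a1 and Fn1 were listed with knowledge of published work on this culture model, so their direction is not independent evidence.

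Enzymes that modify and crosslink collagen fell with it: of 13 tested, 8 fell and 0 rose, and 8 fell adjusted over the list alone. P4ha2, a prolyl hydroxylase subunit, fell from 3015 ± 234 to 2019 ± 157 (log2 fold change -0.58, SE 0.07), and the lysyl hydroxylases Plod2 and Plod1 fell by 0.44 and 0.39 on the log2 scale. The list lay lower than the other genes in limma camera (adjusted p = 0.0077; adjusted p = 0.383 with an estimated correlation). The count of falls was 3 without each of mineralizing cultures 1, 2 and 3, 4 without AEBSF culture 2 or 3, 3 with no signal filter and 2 with a constant variance prior.

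Few genes for proteins that cut the matrix or its precursors passed. Of 22 measured matrix proteases and inhibitors, 11 lay below the signal filter and were not tested. Of 11 tested matrix proteases and inhibitors, only Serpine2, a secreted inhibitor of serine proteases, passed, falling from 4198 ± 66.4 to 3123 ± 48.8 (log2 fold change -0.43, SE 0.05, limma adjusted p = 0.000424). The membrane protease gene Mmp14 stood at 1811 ± 71.4 and 1721 ± 93.6 (limma adjusted p = 0.477), and a second probe set of it had a log2 fold change of 0.425 (limma adjusted p = 0.0625). Of 6 tested proprotein convertases, 0 passed in limma at an adjusted p of 0.05. Mbtps1, the site-1 protease, a serine protease that AEBSF is known to inhibit, had signals of 1888 ± 121 and 1870 ± 124 (log2 fold change -0.01, SE 0.07). Adjusted over the list alone, 1 and 0 passed, and limma camera gave adjusted p = 0.389 for the proteases and 0.646 for the convertases.

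Among genes of osteoblast differentiation and mineralization, 3 of 14 tested fell and 0 rose. Phex, a membrane endopeptidase whose loss causes hypophosphataemic rickets, fell from 2725 ± 77.9 to 1645 ± 72.9 (1.66-fold; log2 fold change -0.73, SE 0.06, limma adjusted p = 3.36e-05). Phospho1, a phosphatase of matrix vesicles, fell 1.31-fold, and Enpp1, which makes the mineralization inhibitor pyrophosphate, fell 1.23-fold. Transcripts of the bone matrix proteins Ibsp (16520 ± 750 and 17100 ± 251) and Spp1 (504 ± 26.7 and 448 ± 48.1) and of the alkaline phosphatase Alpl (2186 ± 33.2 and 2113 ± 159) did not pass, with limma adjusted p = 0.571, 0.297 and 0.643. Dmp1, with signals of 69.3 ± 8.68 and 48.8 ± 6.70, and Bglap lay below the signal filter and were not tested, and Runx2 and Sp7 were not analysed here. Phex was listed with knowledge of published work on this culture model, so its direction is not independent evidence. The list's count was also 3 adjusted over the list alone and 1 with a constant variance prior. Its shift did not pass (limma camera adjusted p = 0.085), but did after quantile normalization, with the filter at the 60th percentile and with the mean of a gene's probe sets (adjusted p = 0.0463, 0.041 and 0.0447; adjusted p = 0.345 with an estimated correlation in the main fit). The Enpp1 call was lost without mineralizing culture 1 or 3 or AEBSF culture 2 or 3 (limma adjusted p = 0.117, 0.0856, 0.0689 and 0.0587).

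Osteocyte markers, genes of the cells that osteoblasts become inside bone, gave 4 falls among 5 tested genes, and all 5 fell adjusted over the list alone. Besides Phex, which is on both lists, Ackr3 fell from 649 ± 22.8 to 413 ± 30.8 (log2 fold change -0.65, SE 0.09). Phex was listed with knowledge of published work on this culture model, so its part in the count and shift is not independent evidence. Sost, which encodes the Wnt antagonist sclerostin, fell from 466 ± 66.5 to 314 ± 20.9 (-0.56, SE 0.12), and the homeobox gene Irx5 fell by 0.61 (SE 0.17) on the log2 scale. Limma camera placed the list lower (adjusted p = 0.000552; adjusted p = 0.221 with an estimated correlation). The count was 2 with a constant variance prior and 2 without mineralizing culture 1, where Sost and Irx5 were lost (limma adjusted p = 0.0555 and 0.0599). The Irx5 call was also lost without mineralizing culture 3 and AEBSF cultures 2 and 3 (adjusted p = 0.128, 0.103 and 0.0761), and a second probe set of Irx5 did not pass in limma (log2 fold change -0.12, adjusted p = 0.788).

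ER chaperones and genes of the unfolded protein response fell together. Of 21 tested, 15 fell and 0 rose, 18 fell adjusted over the list alone, and 20 of the 21 values lay below 0. Sdf2l1 and Herpud1, induced by ER stress, fell from 3810 ± 83.0 to 2476 ± 245 and from 6593 ± 231 to 4416 ± 342 (log2 fold change -0.63 and -0.58, SE 0.07 and 0.06). Sel1l, which acts with Herpud1 in the disposal of misfolded proteins, fell by 0.56 on that scale. Atf6, the ER-bound transcription factor that site-1 protease cuts, fell from 2520 ± 129 to 1837 ± 81.1 (1.37-fold; -0.46, SE 0.06, limma adjusted p = 0.000905). Hspa5, the chaperone BiP, did not pass, with 20320 ± 1090 and 20070 ± 1022 (-0.02, SE 0.06, limma adjusted p = 0.882). Its probe set was among the brightest on the array, where 0 of 126 others at 0.75 times its signal or more held a called fall as large as the list median of -0.32. Limma camera placed the list lower (adjusted p = 1.19e-07; adjusted p = 0.274 with an estimated correlation). With a constant variance prior 6 members fell.

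Other cargo and secretion genes mostly did not pass: of 20 tested genes of COPII vesicles and the secretory pathway, Sec24d fell and Creb3 rose, 1 in each direction also adjusted over the list alone (limma camera adjusted p = 0.492). Sec24d, a coat subunit that large cargo such as procollagen needs, fell from 1859 ± 117 to 1496 ± 103, a call lost without mineralizing culture 2 (limma adjusted p = 0.0701). Creb3, an ER-bound transcription factor, rose from 640 ± 20.1 to 785 ± 15.4, a call lost without mineralizing culture 1 or 2 or AEBSF culture 2 (limma adjusted p = 0.0855, 0.0764 and 0.0521) and with the arrays scaled to hybridization controls (0.433). Creb3l1, a relative that site-1 protease also cuts, stood at 1211 ± 53.4 and 1174 ± 84.9 (limma adjusted p = 0.721).

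Targets of Atf4 and the amino acid response gave 7 falls and 0 rises among 21 tested genes, and 8 falls and 1 rise adjusted over the list alone. Nupr1, a stress-induced chromatin protein, fell from 3122 ± 147 to 1548 ± 225 (2.03-fold; log2 fold change -1.02, SE 0.09, limma adjusted p = 8.32e-05). Asparagine synthetase (Asns) fell 1.33-fold, the pseudokinase gene Trib3 fell 1.29-fold, and Ddit3, which encodes the stress factor CHOP, fell from 12910 ± 364 to 10320 ± 164 (log2 fold change -0.32, SE 0.05). By limma camera this list also lay lower (adjusted p = 0.0219; adjusted p = 0.345 with an estimated correlation), a call lost without mineralizing culture 2 (adjusted p = 0.0568).

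**Figure D2:**
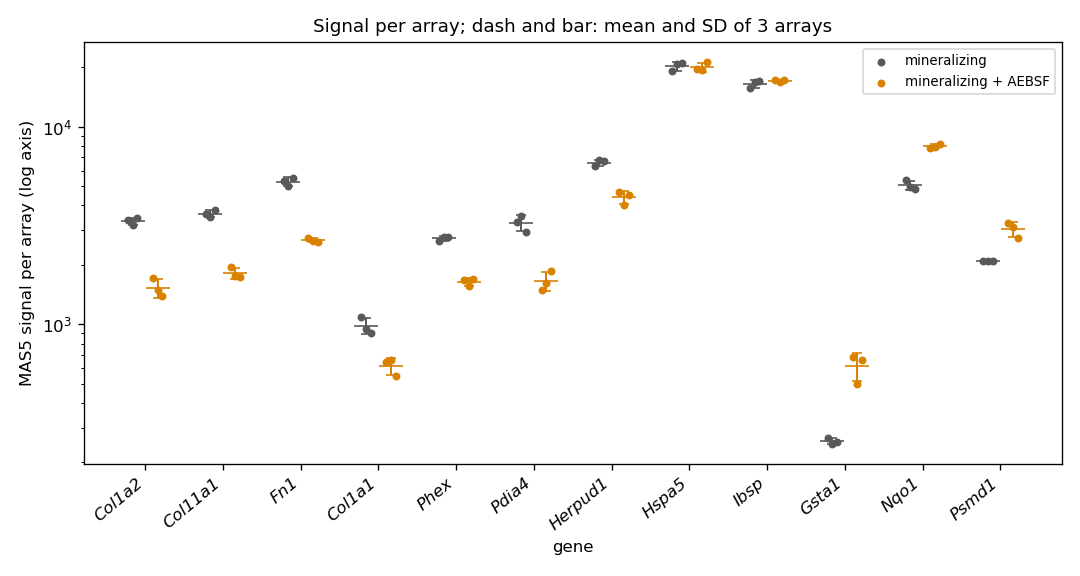
MAS5 signal on each array (y axis, log scale) for 12 genes in the 3 mineralizing (grey) and 3 AEBSF (orange) cultures, with a dash at the mean and a bar of 1 SD. The arrays of the groups lie apart for 10 genes, among them Col1a2 (3334 and 1534) and Nqo1 (5052 and 7971), and they overlap for Hspa5 and Ibsp. The 10 had all passed the threshold and were picked for display, so their separation adds no evidence. Of unchanged genes, 10% would also lie apart by chance.

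In cholesterol synthesis, 5 of 17 tested genes fell and 0 rose, and 5 fell adjusted over the list alone. They were Lss, Tm7sf2, Ebp, Cyp51 and Fdps, which makes farnesyl pyrophosphate; the others act after squalene. Lss, lanosterol synthase, fell from 676 ± 59.0 to 458 ± 48.7 (1.48-fold; log2 fold change -0.56, SE 0.10, limma adjusted p = 0.00492), and Cyp51, lanosterol demethylase, fell from 4939 ± 48.4 to 3993 ± 120 (1.24-fold). A second probe set of Cyp51 did not pass in limma (log2 fold change -0.11, adjusted p = 0.311). Limma camera placed the list lower (adjusted p = 0.0188; adjusted p = 0.345 with an estimated correlation). That call was lost without mineralizing culture 2 (adjusted p = 0.071), as was the Ebp call without mineralizing culture 1 or 2 or AEBSF culture 1 (limma adjusted p = 0.0914, 0.0649 and 0.0586), and 3 members fell with a constant variance prior.

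Transcripts of the SREBP factors and of site-2 protease, which cuts them, narrowly missed the threshold in the main fit and passed it in some others. Srebf1 had signals of 655 ± 102 and 823 ± 51.6 and Srebf2 of 2005 ± 148 and 1723 ± 76.5 (limma adjusted p = 0.0523 and 0.0542). Mbtps2, the site-2 protease, stood at 1081 ± 80.2 and 904 ± 69.0 (limma adjusted p = 0.0529). With the filter at the 60th percentile all 3 passed (limma adjusted p = 0.0439, 0.0388 and 0.042). Srebf1, higher with AEBSF, also did so after quantile normalization, median centring or with a robust prior (0.0478, 0.0413 and 0.0499). Srebf2 and Mbtps2, lower with AEBSF, did so with the mean of a gene's probe sets (0.0424 and 0.0402) and the hybridization scaling (0.0201 and 0.00882). Without 1 array, Srebf1 and Srebf2 passed without mineralizing culture 2 (0.0174 and 0.0463) and Mbtps2 without AEBSF culture 3 (0.0284). Insig1, an ER protein whose gene is a target of SREBP, stood at 2472 ± 74.7 and 2679 ± 210 (limma adjusted p = 0.27). A second Srebf1 probe set had a log2 fold change of -0.07. In the list of sterol uptake and sensing, Scarb1 and Scap rose and Insig2 fell among 9 tested genes (2 higher and 4 lower adjusted over the list alone; limma camera adjusted p = 0.518). Scarb1, the HDL receptor, rose from 838 ± 57.4 to 1092 ± 7.51, and Insig2 fell from 3910 ± 119 to 3035 ± 78.2. The Scap call (limma adjusted p = 0.0381) was lost without mineralizing culture 1, 2 or 3 or AEBSF culture 1 or 2 (0.115, 0.0989, 0.0971, 0.121 and 0.0536) and with the mean of its probe sets (0.116), and neither rise passed with the arrays scaled to hybridization controls (0.138 for Scarb1). Hmgcs1 was not analysed here.

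Fatty acid synthesis gave 3 falls among 15 tested genes, with 5 falls and 2 rises adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate in the cytosol, fell from 452 ± 15.5 to 204 ± 26.1 (2.23-fold; log2 fold change -1.16, SE 0.12, limma adjusted p = 0.000244). The desaturase gene Fads1 fell 1.28-fold and Acsl3 fell 1.24-fold. Of 6 tested targets of the oxysterol receptor LXR, 2 fell, also adjusted over the list alone: the cholesterol exporter Abca1, from 612 ± 34.5 to 397 ± 13.9, and Lpcat3, from 1937 ± 166 to 1622 ± 123. Neither list's shift passed (limma camera adjusted p = 0.164 and 0.183). The Lpcat3 call was lost after quantile normalization and median centring (limma adjusted p = 0.0564 and 0.0668), without mineralizing culture 2 or 3 or AEBSF culture 1 or 3 (0.107, 0.167, 0.0972 and 0.122).

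The subunits of the proteasome, the complex that degrades ubiquitinated proteins, rose together: 11 of 20 tested genes rose, 0 fell and all 20 values lay above 0. Psmd1 rose from 2093 ± 10.9 to 3041 ± 260 (limma adjusted p = 0.000568), and Psmd14 and Psmb2 rose 1.31- and 1.27-fold. Adjusted over the list alone, 16 rose, and limma camera placed the list higher (adjusted p = 8.02e-07; adjusted p = 0.321 with an estimated correlation). The count was 7, 5 and 7 without mineralizing culture 1 or 2 or AEBSF culture 2, 7 with no signal filter, and 2 with a constant variance prior. Of the other probe sets of Psmd14, 1 passed as well and 1 had a log2 fold change of -0.04. With the arrays scaled to hybridization controls 1 member rose, with a list median of 0.07 and a median SE of 0.089, against 0.216 and 0.057 in the values as deposited. After quantile normalization 9 rose, and the median of 0.144 lay 0.143 above that of all genes, against 0.213 before.

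Genes of the antioxidant response under the factor NRF2 gave 4 rises and 1 fall among 14 tested, and 7 rises and 1 fall adjusted over the list alone. Nqo1, a quinone reductase, rose from 5052 ± 271 to 7971 ± 177 (1.58-fold; log2 fold change 0.66, SE 0.05, limma adjusted p = 4.39e-05), and Gclc, which makes the glutathione precursor, rose from 1214 ± 74.6 to 1594 ± 53.4. Osgin1 and Txnrd1 also rose, and Slc7a11, the cystine transporter, fell from 1168 ± 20.5 to 957 ± 64.9. The list lay higher in limma camera (adjusted p = 0.0188; adjusted p = 0.274 with an estimated correlation). Without mineralizing culture 1 or AEBSF culture 1, with no filter or with a constant variance prior 2 rose, and with the hybridization scaling 1 rose. Osgin1, Txnrd1 and Slc7a11 lost their calls without mineralizing culture 1 or 2 or AEBSF culture 1 or 2 (limma adjusted p from 0.0511 to 0.156), and Osgin1 and Slc7a11 also without mineralizing culture 3 (0.0689 and 0.0591).

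Heat shock genes gave 4 rises and 0 falls among 10 tested, and 7 rises adjusted over the list alone. The cytosolic chaperone gene Hsph1 rose from 5285 ± 154 to 7175 ± 280 (1.36-fold; log2 fold change 0.44, SE 0.05), the Hsp70 co-chaperone gene Bag3 rose 1.39-fold, and the mitochondrial chaperonin genes Hspd1 and Hspe1 rose 1.19- and 1.17-fold. As a group they lay higher in limma camera (adjusted p = 0.00775; adjusted p = 0.349 with an estimated correlation). Without mineralizing culture 1 or 2 or AEBSF culture 2, Hspd1 and Hspe1 lost their calls and 2 members rose. Hspe1 also lost its call without AEBSF culture 1 (limma adjusted p = 0.0584), and 1 member rose with a constant variance prior or with the hybridization scaling.

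The cell cycle lists went in opposite directions. Of 18 tested genes of DNA replication 8 rose and 0 fell, among them the helicase subunits Mcm6 (6786 ± 188 to 8820 ± 437; log2 fold change 0.38, SE 0.05), Mcm3 (0.37, SE 0.06) and Mcm2 (0.29, SE 0.05). Of 19 tested genes of mitosis 6 fell and 1, Ccna2, rose; Nusap1, a spindle protein, fell from 1919 ± 42.1 to 1439 ± 112 (-0.42, SE 0.07). Mki67, a proliferation marker, stood at 2361 ± 46.6 and 2190 ± 167 (limma adjusted p = 0.282). Adjusted over the list alone, 8 replication genes rose and 2 fell, and 8 mitosis genes fell and 1 rose.

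Limma camera placed the replication list higher (adjusted p = 0.0244; adjusted p = 0.376 with an estimated correlation) and the mitosis list lower (adjusted p = 0.0188; adjusted p = 0.349 with an estimated correlation). The replication call was lost without mineralizing culture 1 or AEBSF culture 3 (camera adjusted p = 0.0774 and 0.0749) and the mitosis call without AEBSF culture 1 (0.0682). Counts of replication genes that rose were 4, 5 and 5 without mineralizing culture 1 or 2 or AEBSF culture 2, 2 with a constant variance prior and 0 with the hybridization scaling, which also turned the list median from 0.11 to -0.04. In 10000 random lists matched on signal, the central 95% of medians ran from -0.078 to 0.11, which held the replication median of 0.108. Counts of mitosis genes that fell were 3, 2 and 3 without mineralizing culture 1, 2 or 3 and 1 with a constant variance prior. The Ccna2 rise was lost without mineralizing culture 1, 2 or 3 or AEBSF culture 2 or 3 (limma adjusted p = 0.107, 0.0542, 0.0573, 0.0704 and 0.0677) and with the hybridization scaling (0.63).

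Immediate early genes gave 3 falls, Fos, Jun and Klf4, and 0 rises among 17 tested, and 7 falls adjusted over the list alone. Klf4, a zinc finger transcription factor, fell from 3753 ± 108 to 3102 ± 190 (log2 fold change -0.28, SE 0.06). Limma camera placed the list lower (adjusted p = 0.0188; adjusted p = 0.349 with an estimated correlation), a call lost without mineralizing culture 3 (adjusted p = 0.0666) and with the hybridization scaling (0.0733). Fos (limma adjusted p = 0.0434) lost its call without any 1 of the 6 arrays, with adjusted p from 0.0661 without AEBSF culture 2 to 0.135 without mineralizing culture 3. Jun lost its call without mineralizing culture 1, 2 or 3 (limma adjusted p = 0.0506, 0.0534 and 0.0531) and with the mean of its probe sets (0.573), of which the others had log2 fold changes of -0.17 and 0.20 and did not pass. Targets of YAP and SRF, factors that respond to cell shape and tension, gave 3 falls and 0 rises among 10 tested (7 falls and 1 rise adjusted over the list alone). They were the actin-binding genes Flna, from 2419 ± 122 to 1859 ± 165, and Tpm1, and the YAP target Amotl2, from 2617 ± 77.4 to 2186 ± 102. Limma camera placed that list lower (adjusted p = 0.0188; adjusted p = 0.274 with an estimated correlation), a call lost without mineralizing culture 1 (adjusted p = 0.0526), where 1 member fell; with a constant variance prior 0 fell. Tpm1 lost its call without any 1 array but AEBSF culture 1, with limma adjusted p from 0.0836 to 0.128, and 0 of its 4 other probe sets passed.

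Targets of BMP and TGF-beta went both ways, with 4 rises and 3 falls among 17 tested genes (5 and 5 adjusted over the list alone) and a list median of 0.02 (limma camera adjusted p = 0.953). Id1 and Id2, inhibitors of differentiation induced by BMP, rose 1.35-fold each, from 1176 ± 47.8 to 1592 ± 170 and from 2759 ± 61.0 to 3739 ± 501; the other rises were Smad7 and Id3, the latter named after its values were seen. The Smad7 call was lost without mineralizing culture 3 or AEBSF culture 1 or 2 (limma adjusted p = 0.0591, 0.0629 and 0.0564) and with the mean of its probe sets (0.12), of which the other 2 did not pass. The ligand gene Bmp4 fell from 2060 ± 39.2 to 1496 ± 123 (log2 fold change -0.47, SE 0.07). Nog, a secreted BMP antagonist, fell from 2715 ± 113 to 2196 ± 169, a call lost without mineralizing culture 2 (limma adjusted p = 0.0578), where 1 member fell. The other fall was Tgfbi, lost without mineralizing culture 1, 2 or 3 or AEBSF culture 1 or 3 (limma adjusted p = 0.0707, 0.0928, 0.0939, 0.0656 and 0.0704) and with no filter (0.0755). The number that rose was 2 without mineralizing culture 3 or AEBSF culture 2, and 0 with a constant variance prior or with the hybridization scaling, under which the list median was -0.12.

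In the other pathway lists, few genes passed and no shift did. Many members were too dim to test: 12 of 17 measured NF-kB and inflammation genes and 7 of 16 interferon response genes lay below the signal filter. Of 11 tested targets of p53, 1 fell (limma camera adjusted p = 0.492); it was Phlda3, whose call was lost without mineralizing culture 1, 2 or 3 or AEBSF culture 2 or 3 (limma adjusted p = 0.0941, 0.126, 0.0979, 0.0877 and 0.0906). Of 5 tested NF-kB and inflammation genes Icam1 rose and Nfkbia fell (camera adjusted p = 0.953), and both calls were lost without any 1 of the 6 arrays, with limma adjusted p from 0.0718 to 0.157 and from 0.0529 to 0.158. Of 9 interferon response genes Gbp2 fell, from 919 ± 32.7 to 718 ± 35 (camera adjusted p = 0.953). Among 16 lysosomal genes Ctsa, a lysosomal carboxypeptidase, fell from 4460 ± 119 to 3741 ± 182 and Sqstm1, an autophagy adaptor, rose (camera adjusted p = 0.143). The Sqstm1 call was lost without mineralizing culture 1 or 2 or AEBSF culture 1 or 2 (limma adjusted p = 0.0815, 0.0978, 0.0674 and 0.0629) and with the mean of its probe sets (0.126). Of 10 tested Wnt targets and of 16 genes of hypoxia and glycolysis 1 each fell, the cyclin gene Ccnd1 and the kinase gene Pdk1, named after their values were seen (camera adjusted p = 0.953 for both). Without mineralizing culture 2 or 3, 0 Wnt targets fell. The Wnt median of 0.02 and camera's downward direction differ in sign, as do the median of 0.01 and the mean of -0.004 of the hypoxia list. Among 13 ribosomal protein genes 0 passed in limma at an adjusted p of 0.05 and all values lay above 0. Their median was 0.09 (camera adjusted p = 0.0642; adjusted p = 0.702 with an estimated correlation; 0.00218 without mineralizing culture 3, 0.0313 without AEBSF culture 1 and 0.0451 with no filter). It was -0.02 after quantile normalization (camera adjusted p = 0.859) and -0.06 with the hybridization scaling. Random lists matched on signal gave medians from 0.083 to 0.119 in their central 95%. These genes are among the brightest, and draws past the top of the signal order fell back on the brightest gene. List members could be drawn too, so that range is no measure of chance for this list. Adjusted over the list alone, lysosomal genes gave 1 rise and 3 falls, and the counts of the other lists of this kind were as given.

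Markers of other cell types were mostly dim. Of the chondrocyte list 4 of 10 measured genes were bright enough to test, and Sox6, a transcription factor of cartilage, fell from 1548 ± 42.1 to 813 ± 61.9 (1.91-fold; log2 fold change -0.93, SE 0.07, limma adjusted p = 2.57e-05). In limma 0 of 3 tested adipocyte markers passed an adjusted p of 0.05, and 0 of the 1 tested each for macrophages and osteoclasts, muscle and endothelium, the same counts as over the list alone, where Sox6 also passed. Csf1r, the macrophage receptor, stood at 120 ± 50.3 and 92.9 ± 6.45.

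Among genes past the threshold whose arrays of the groups lay apart, the largest rise with both groups above 67.2, the signal at the filter, was that of Gsta1. Cbr3, a carbonyl reductase, rose from 41.2 ± 12.9 to 134 ± 17.5 (limma adjusted p = 0.00283), but its mineralizing signal lay below 67.2, so the size of the change is not given. Mcrip2 rose from 792 ± 33.6 to 1515 ± 44.3 (1.91-fold), and Klhl21, an adaptor of a ubiquitin ligase, rose 1.73-fold. Likewise Acss3, a mitochondrial acyl-CoA synthetase, fell from 151 ± 12.1 to 59.8 ± 22.7 (limma adjusted p = 0.00918; 0.053 with a constant variance prior), with an AEBSF signal below 67.2. Selenop, which encodes a secreted selenium carrier, fell from 705 ± 44.7 to 309 ± 23.1 (2.28-fold). Pygl, a glycogen phosphorylase, fell from 1233 ± 54.6 to 563 ± 80.9 (2.20-fold), and the transmembrane collagen gene Col13a1 from 221 ± 25.5 to 99.6 ± 4.18 (2.21-fold). The sodium channel genes Scn7a and Scn1a fell 2.40- and 2.10-fold. On the AEBSF arrays Scn7a stood at 58.7, 59.7 and 92.3, close to 67.2, so the size of its fall is uncertain. Of the 15 largest rises, 5 (Mapt, Fxr2, Mark1, Asic1 and Cyp27b1) were lost without at least 1 array, as were 4 of the 15 largest falls (Dapk2, Plppr3, Styxl1 and Cgnl1). Mapt, for example, had a limma adjusted p of 0.0343 with all arrays, and 0.11, 0.093, 0.0573, 0.102 and 0.065 without mineralizing culture 2 or 3 or AEBSF culture 1, 2 or 3.

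The arrays separated by group. The first principal component held 39.6% of the variance, with scores from -20 to -16.8 for the mineralizing cultures and from 14.9 to 20.3 for the AEBSF cultures. Correlations across probe sets, which are not independent replicates, were 0.986 to 0.990 within groups and 0.979 to 0.984 between them. As a sign of RNA quality, the log2 ratio of 3' over 5' signal was 0.61 in both for beta-actin and 0.05 ± 0.03 and 0.10 ± 0.02 for Gapdh (exact permutation p = 1 and 0.2, two-sided, smallest possible 0.1). The hybridization controls were 0.15 higher with AEBSF on the log2 scale (10.9 ± 0.09 and 11.1 ± 0.08, exact permutation p = 0.2).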

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

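A control probe set for 5S ribosomal RNA, which entered none of the comparisons, was flagged as a signal outside the main measurement. Its signal was 364 ± 37.2 in the mineralizing cultures and 427 ± 18.6 in the AEBSF cultures, a difference of 63.2. All 3 AEBSF arrays, at 406 to 440, lay above all 3 mineralizing arrays, at 332 to 404, and the exact permutation p of 0.1 (two-sided) is the smallest that 3 against 3 can give. It was not adjusted for the number of array measures compared. Hybridization controls and poly-A controls, a further set of control transcripts, were also higher with AEBSF, by 0.146 and 0.183 on the log2 scale (exact permutation p = 0.2 and 0.5). The 5S difference may thus be shared in part with other controls.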

How the results depend on the processing

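Of 122 named genes past the threshold, 53 kept their call in every one of the 17 alternatives that gave them a value, and 0 of the 122 calls reversed. Among all 1608 genes past the threshold, 13 changed sign with the mean of a gene's probe sets. Calls of named genes lost numbered 4 with quantile normalization, 5 with median centring, 0 with 16 or 64 added, 24 with no filter, 1 with the robust prior, 59 with the constant prior, 8 with the mean of a gene's probe sets, 16 with the replicate block, 29 with the hybridization scaling and 15 to 36 with 1 array left out; the filter at the 60th percentile left 20 without a value. Of 36 named genes that did not pass, 5 (Srebf1, Srebf2, Mbtps2, Tpi1 and Znrf3) did in at least 1 alternative. The fall in collagens and matrix proteins (9 of 15) moved by more than 1.5 times under none of these. Without the trend of the variance prior, 885 probe sets passed, 285 higher and 600 lower, 6 of the higher ones at least 2-fold, as did 544 genes, 145 higher and 399 lower, and of listed genes 9 rose and 38 fell. Of the 1608 genes 521 were shared. With the correlation between genes estimated, 0 lists were shifted higher and 0 lower, against 4 and 9, while fry, which tests lists against no change, called 4 and 13.

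With no filter, 710 probe sets and 440 genes were higher, 24 of them listed, and 80 probe sets changed at least 2-fold, 25 higher. With the filter at the 60th percentile, 18 did, 3 higher and 15 lower. Adding 16 to each signal left 29 at 2-fold or more, 20 of them lower, and adding 64 left 11, 4 higher and 7 lower, since an added constant shrinks the fold of dim probe sets. Scaling to the hybridization controls, chosen after seeing the data, gave 119 probe sets higher and 2457 lower, 113 at least 2-fold of which 102 were lower, and 61 genes higher and 1535 lower; of listed genes 3 rose. It shared 970 of the 1608 genes and shifted every gene's log2 fold change alike, so differences between genes stayed as they were. No count of cells entered either scaling, so neither gives amounts per cell.

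Leaving out 1 array at a time leaves fewer samples, and gave 1203 to 2257 probe sets (489 to 997 higher, 714 to 1260 lower) and 790 to 1460 genes (292 to 643 higher, 498 to 817 lower). The lowest counts came without mineralizing culture 1, and 1239, 1502 and 1626 probe sets passed without mineralizing culture 2 or 3 or AEBSF culture 1. At least 2-fold were 45 to 68 probe sets, 6 to 14 of them higher, the 6 without AEBSF culture 1, and 19 to 34 listed genes rose, 19 without mineralizing culture 1, 20 without mineralizing culture 2 and 21 without AEBSF culture 2.

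Replicate numbers are shared between the groups, but same-numbered cultures did not deviate together: correlations of their deviations were 0.011, -0.119 and -0.036, and 0 of 6 arrays correlated best with its own number. With the replicate number as a block, 1802 probe sets and 1154 genes passed, 1123 of them among the 1608, and 13 lists were shifted as without it. Signal over background limits what could be seen: 9 of 24 measured matrix genes and most markers of other cell types lay below the filter, and so did Dmp1.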

Other observations

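Grouped by the stem of the symbol, a description made after seeing the data, 4 of 322 tests over 161 families with at least 8 tested genes passed (Fisher's exact test, one-sided, adjusted over all 322). The test counts the genes of a family as independent. Genes measured on the same 6 arrays can vary together, so its p-values may be too small. The overlapping matrix and proteasome lists did not pass in limma camera with an estimated correlation (adjusted p = 0.221 and 0.321). Of 19 genes for collagen chains 12 fell and 0 rose (adjusted p = 1.54e-06), and 6 of the 12 were not on the matrix list. These were the transmembrane collagens Col13a1 and Col25a1, the basement membrane chain Col4a5, Col8a2, Col22a1 and Col24a1. Col22a1 fell from 652 ± 13.5 to 334 ± 47.6 (log2 fold change -0.98, SE 0.11) and the fibrillar Col24a1 from 1109 ± 24.7 to 591 ± 45.4 (-0.91, SE 0.08). Without 1 array, 11 or 12 collagen genes fell. Each of the 6 was singled out after its values were seen.

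On the rising side, regulatory subunits of the proteasome (10 of 14, adjusted p = 7.45e-07), translation initiation factors (12 of 48, with 2 that fell, adjusted p = 0.0102) and splicing factors of the Sf3 group and relatives (5 of 10, adjusted p = 0.0265) passed. Among the initiation factors, Eif3c rose from 7646 ± 378 to 9431 ± 524 (log2 fold change 0.30, SE 0.06) and Eif5b from 1430 ± 109 to 1836 ± 137 (0.36, SE 0.08). The cap-binding Eif4e3 fell from 464 ± 40.5 to 273 ± 37.7 (-0.77, SE 0.12) and Eif1a fell from 2805 ± 76.6 to 2352 ± 65.9. The splicing factor gene Sf3b4 rose from 2752 ± 24.7 to 3455 ± 200 (0.33, SE 0.06). These counts were fragile: without mineralizing culture 1, 2 or 3 or AEBSF culture 1 or 2 they were 4, 4, 5, 6 and 5 for the proteasome subunits and 3, 2, 2, 3 and 2 for the splicing factors. For the initiation factors they were 6 and 4 without mineralizing culture 1 or 2. In the order proteasome, initiation and splicing they were 6, 7 and 3 with no filter and 7, 7 and 2 with the replicate block, and with a constant variance prior the 3 counts were 3, 1 and 0. With the arrays scaled to hybridization controls 1, 0 and 0 rose and the median of the initiation factors turned from 0.10 to -0.05. After quantile normalization it was 0.05, and lay 0.047 above that of all genes, against 0.094 in the values as deposited.

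Of the tests that follow, those of the count of probe sets over other splits, of array scaling for the proteasome and of the sterol genes were chosen after the result was seen. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05, and in each test 1 of the 10, the real one, gave the largest result. The real split gave 2495 probe sets, 50 probe sets at least 2-fold and 1608 genes, and the highest of the other 9 gave 0 of each in limma, with 358 to 725 probe sets at an unadjusted p under 0.05 against 5290. It gave 13 shifted lists by camera with the preset correlation, and the highest other gave 7. Each of the other 9 splits mixes arrays of both groups, so a difference between the groups adds to their residual spread. That lowers their counts of probe sets and genes, which are therefore no measure of what chance would give.

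Hspa5 did not pass while 15 of 21 ER genes fell, although BiP, its product, is induced with them in ER stress. A ceiling on bright probe sets may hide a fall, and the values do not settle it. Of the 126 other probe sets at 0.75 times the signal of Hspa5 or more, 8 passed, 0 of them lower, so bright probe sets could still rise. The highest signals of the arrays, from 23976 to 29978, also lay above that of Hspa5. Yet the log2 fold changes of the 126 had an SD of 0.06, 0.365 times that of 481 dimmer probe sets, and 0 had a called fall as large as the list's median. That is what saturation needs, but the bright group also holds genes that many cells express steadily, such as those for ribosomal proteins, so a true lack of change in Hspa5 with AEBSF stays open. The same limit holds for Ibsp, at 16520 ± 750 and 17100 ± 251.

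Of 20 tested proteasome genes 11 rose, 0 fell and 9 did not pass. A factor per array moves all genes alike and cannot part the list from the rest, yet its median lay 0.213 above that of all genes. Scaling to the hybridization controls, which cannot alter that distance, ended 10 of the 11 calls. It lowered the list's median from 0.216 to 0.07, and the controls' spread within groups raised the members' median SE from 0.057 to 0.089. With the shift between group means alone 3 members rose, and with the full scaling 1. Bright genes lay higher in general, since random lists matched on signal had a median of 0.07. The list's median stood at percentile 100 of 10000 such lists, whose upper bound was 0.14. Those lists drew genes independently, while the proteasome genes had an estimated correlation of 0.242. Medians of genes that vary together spread more widely, so the percentile cannot exclude that a trend with signal and shared variation gave the rise. Quantile normalization, which can remove such a trend, shrank the distance to 0.143 and left 9 rises and the list's shift in limma camera (adjusted p = 8.2e-05), so a trend may account for part of the rise. What stays open, as a hypothesis found on the same data and not itself tested, is that the cells may respond to AEBSF, a reactive protease inhibitor, with new proteasome subunits, as they do when the proteasome is inhibited. No measure of protease activity was analysed here, and the estimated correlation between genes left the list's shift at adjusted p = 0.321.

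The 5 cholesterol genes that fell may reflect less cutting of SREBP by site-1 protease. If all 17 tested transcripts had changed by 1 common amount, they would be alike within their spread. Their weighted mean was -0.154, and 8 of the 17 had a 95% confidence interval that left it out, 5 below and 3 above, where up to 3 would be expected if the members were alike and independent. They ran from -0.56 for Lss to 0.14 for Sqle, the latter named after its values were seen. This argues against 1 common change of the transcripts at 12 h. It cannot decide on an equal loss of transcription, since transcripts that decay at different rates would differ under it too. A loss that differs from gene to gene also stays open. Less SREBP would also lower Insig1, a target of SREBP fixed by name, whose 95% confidence interval ran from -0.026 to 0.254 and held no fall as large as that mean. A partial or passing effect of AEBSF on SREBP and an effect on single enzymes by another route both stay open.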
